A study of Mus musculus with 360 samples.

How the data were processed

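The series profiled 360 single cells from the cochlea of adult mice, 180 of each of 2 genotypes, and every deposited sample is 1 cell. Per the labels, cells were sorted on tdTomato and EpCAM fluorescence into 96-well plates after papain dissociation, and libraries were made by SMART-MATQ, a method that primes along whole transcripts and carries unique molecular identifiers (UMIs). Control animals carried Fbxo2CreERT2, a tamoxifen-inducible Cre recombinase driven from the Fbxo2 locus, and the Rosa26 tdTomato reporter. GAP animals carried in addition a Rosa26 allele with Gfi1, Atoh1 and Pou4f3. Tamoxifen was given at 3 weeks of age and cells were collected at 5 weeks.

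The deposited matrix holds UMI counts of exons per gene and cell, with no normalization by the authors. Per the submitters' processing notes, STAR and HTSeq were used with the mm10 build. Their versions, the annotation release, the way reads were collapsed to UMIs and the use of strand are not given in the sources used here. All 360 columns of counts were matched to a sample by title, and the matrix has no row that is not a gene. The authors' deposited annotation assigns 341 of the cells to 9 clusters, each with a number and a name. These assignments were used as given, including their names. The 19 cells without a cluster stayed in comparisons of whole genotypes and in no comparison of clusters. No 2 columns of counts were identical. No doublet caller was run. Cells were sorted singly, and cells with very high counts are weighed in the closing section.

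The labels name no animals, so each genotype counts as 1 sample and cells are not replicates. No test was made and no p-value is given for any difference between genotypes. UMIs were summed over the cells of a set and scaled by its total to CPM, so that every set sums to the same value. A ratio of 2 sums has the exact conditional-binomial 95% interval, a level the exact Poisson interval and a share of cells the exact Clopper-Pearson interval. All of these cover counting error only, and not variation between animals or plates. A count of 0 is given with the limit of 3 counts over the set, and a fold against 0 counts is a lower bound computed from that limit over the genotype. This bound leaves out the counting error of the higher level and is less strict than the 95% interval. For Atoh1 it is 1074, and the lower end of the interval is 873. Log2 ratios add 1 CPM to both levels. The titles carry letters, A and B for control and C and D for GAP, followed by a well number, and the letters were read as plates. Since each letter holds 1 genotype, plate and genotype cannot be told apart, and values are shown per letter and for the 4 pairings of a GAP letter with a control letter.

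Genes, lists and rules were fixed before the data were examined. Genes named in a comparison of genotypes are Atoh1, Gfi1, Pou4f3, Fbxo2 and Epcam. To these come the 12 highest and 12 lowest log2 ratios among genes with at least 10 CPM in a genotype, a UMI in at least 5 cells of the higher genotype, no cell with more UMIs than the sum of the other cells of that genotype divided by 2, and the same direction in all 4 pairings. Predicted genes are left out, and some genes that the rule names are not reported here. Within a cluster the numbers are 6 and 6, the letter condition applies only where each letter has 5 cells there, and a comparison needs at least 10 cells of each genotype. From each of 23 gene lists the 4 members with most UMIs may be named, and 8 from the 5 hair cell lists. All 329 listed genes are in the matrix. Of a list, members at 10 CPM or more in a genotype enter the median log2 ratio. The median is set against 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. For shares of cells with a UMI and for genes detected per cell, each cell was thinned to 8000 UMIs without replacement, which left out 3 control cells and 0 GAP cells. Hair cell genes per cell were counted over the 75 genes of the fate, bundle and synapse lists other than the 3 transgene genes, of which 73 have a UMI.

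The ratio computation was tested on simulated counts for the population comparison. Of 8670 genes at 10 CPM or more, 95.2% of the 95% intervals held the true fold, and of 50 genes simulated at 2-fold, 100% came within 0.5 of the true log2 fold. Of 8470 unchanged genes, 0.0236% came out at 2-fold or more. The simulated counts were Poisson draws around pooled levels, without variation between cells, letters or animals. These shares therefore describe counting error alone and not the error to be met in the measured cells.

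Alternatives were the mean of per-cell CPM, scaling by trimmed mean of M values (TMM, edgeR 4.0.16) or median of ratios, a minimum of 5000 UMIs per cell, thinning to 8000 or 4000 UMIs, each letter left out, a pseudocount of 10 CPM, a filter of 50 CPM or none, the log2 ratio of summed CPM of a list, and an own Leiden clustering (scanpy 1.11.5, 2000 variable genes, 20 components, 15 neighbours). Added after seeing the data were cells with a deposited cluster, cells with at least 15000 UMIs, removal of mitochondrial and abundant nuclear RNAs, removal of clusters 5 and 8, lists without the transgene genes, all cells of a genotype as the denominator of shares, and own clusters with no control cell. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3. Gene positions come from GENCODE release M21 on GRCm38, the assembly called mm10, and were matched by gene identifier without its version.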

Results

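The data are UMI counts of 360 cochlear cells, 180 from control mice and 180 from GAP mice, in which Cre activity also switches on Gfi1, Atoh1 and Pou4f3, the transcription factors that drive hair cell formation. The control cells held 4001274 UMIs and the GAP cells 5366362. A control cell held a median of 21280 UMIs (range 6985 to 55129) and 3721.5 genes, and a GAP cell 28963 UMIs (range 8550 to 60218) and 4910 genes. Median UMIs per cell were 19356 and 22657 in letters A and B (91 and 89 control cells) and 31683 and 27394 in letters C and D (92 and 88 GAP cells). There are no replicate animals in the labels, so the intervals below describe counting error alone.

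The first comparison asked whether the genes of the GAP allele were present where the labels place them. Atoh1 was at 805 CPM in GAP cells (95% interval 782 to 830, 4322 UMIs) and had 0 UMIs in control cells, at least 1074-fold higher. Pou4f3 was at 583 CPM (563 to 604) against 0 UMIs, at least 778-fold higher. Gfi1 was at 203 CPM (192 to 216) against 1 UMI, 0.25 CPM, in control cells, a ratio of 814 (145.8 to 32189, and 404 without letter B). These exon counts do not separate transcripts of the allele from those of the endogenous loci, which lie on mm10 chromosome 6 at 64729125 to 64731245 (Atoh1), chromosome 18 at 42394539 to 42397249 (Pou4f3) and chromosome 5 at 107716657 to 107726036 (Gfi1). The 2 GAP letters were alike for Atoh1, at 806 CPM in C and 805 in D, while Pou4f3 was at 634 and 522 CPM and Gfi1 at 221 and 182.

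Most GAP cells held these transcripts. A UMI of Atoh1 was found in 91.7% of the 180 GAP cells (86.6 to 95.3), and in 80% once every cell was thinned to 8000 UMIs. For Pou4f3 the shares were 91.7% and 76.1%, and for Gfi1 77.8% and 62.8%. In control cells the share was 0 of 180 for Atoh1 and Pou4f3, which allows up to 1.67%. The 38 GAP cells that the authors placed in clusters shared with control cells are given for comparison within the same plates; whether their UMIs of these genes come from the cells themselves is open, and the authors' clustering can have used such genes. Their median depth was 24124 UMIs, against 28963 in all GAP cells, and 71.1% of them had a UMI of Atoh1 (44.7% after thinning) at a pooled level of 69.2 CPM (53.4 to 88.2). The same share was 78.9% for Pou4f3 (36.8% after thinning) and 42.1% for Gfi1 (15.8%). Fbxo2, whose locus drives the Cre (mm10 chromosome 4, 148160621 to 148166424), was at 410 CPM in GAP and 696 CPM in control cells, 1.70-fold lower in GAP (1.61 to 1.80). Epcam, the surface protein used in the sort, was at 177.8 and 189.9 CPM, a ratio of 0.936 (0.850 to 1.03) whose interval includes 1.

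**Figure D1:**
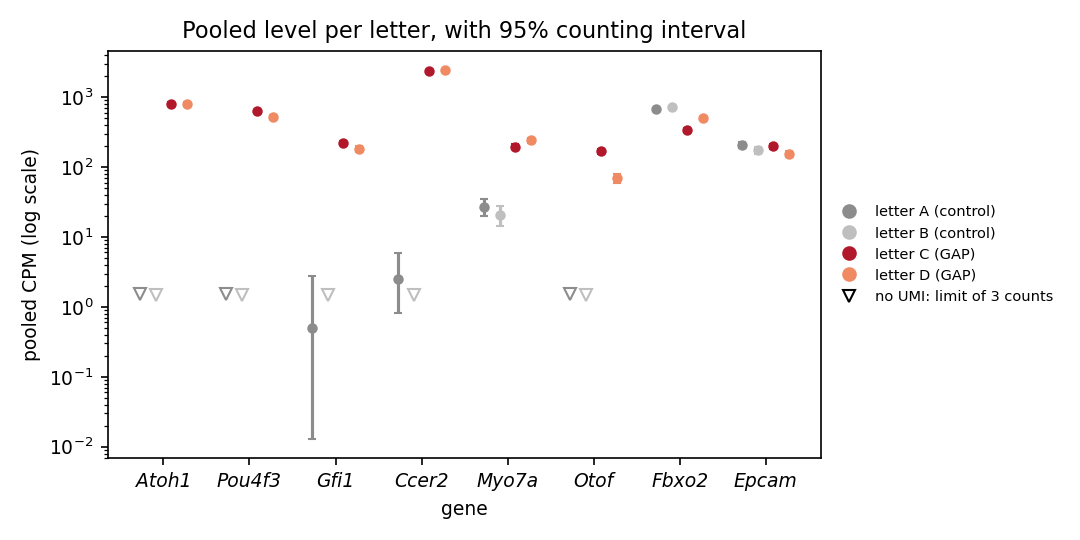
Pooled level in CPM (log axis) of 8 genes in each of the 4 letters, with 95% Poisson intervals; open triangles mark letters with no UMI at the limit of 3 counts. Atoh1 lies at 806 and 805 CPM in the GAP letters C and D and has no UMI in A and B, while Fbxo2 and Epcam are present in all letters.

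The second comparison set all GAP cells against all control cells. GAP cells carried high levels of hair cell genes that control cells nearly lacked. Ccer2, a coiled-coil protein gene of the synapse list, was at 2423 CPM against 1.25 CPM (5 UMIs), 1939-fold higher (831 to 5972); the control UMIs were all in letter A, and the ratio was 961 without letter B. Ptprq, a receptor phosphatase of the hair bundle, was at 310 CPM against 0 UMIs, at least 413-fold higher. In the other direction Ceacam16, a protein of the tectorial membrane that supporting cells secrete, was at 53.5 CPM in GAP and 834 CPM in control cells, 15.6-fold lower (13.8 to 17.7, and 23.7-fold without letter D).

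With Atoh1, Pou4f3 and Gfi1, the genes with the highest ratios included Rasd2, a small GTPase, at 543 against 1 CPM (543-fold, 212 to 1995), and Tmem255b, at 895 against 2.25 CPM (398-fold, 210 to 871). With so few control UMIs these ratios moved when letter A or B was left out, to 1095 and 359 for Rasd2 and to 258 and 888 for Tmem255b. Miat, a long non-coding RNA, was at 522 CPM with 1 UMI in control cells, a ratio of 2088 (375 to 82520), and Kcnh6, a potassium channel of the erg family, was at 234 CPM with 1 control UMI, a ratio of 936 (167.6 to 36989). These became 1036 for Miat without letter B and 472 for Kcnh6 without letter A. Runx1t1, a transcriptional co-repressor, was at 211 CPM and Mfng, a glycosyltransferase that modifies Notch receptors, at 141.1 CPM, both with 0 control UMIs and so at least 281-fold and 188-fold higher.

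Genes lower in GAP cells included several that were abundant in control cells. Ppp1r1b, an inhibitor of protein phosphatase 1 also called DARPP-32, was at 11.2 CPM against 370 CPM, 33.1-fold lower (25.6 to 43.6), and Ltbp2, a matrix protein that binds latent TGF-beta, at 13.4 against 317 CPM, 23.6-fold lower (18.6 to 30.4). Plekhd1 was 13.7-fold lower (10.5 to 18.1) and Entpd8, an ectonucleotidase, 31.6-fold lower (19.2 to 55.9). Slc5a11, a sodium and inositol cotransporter, was 20.1-fold lower (12.9 to 33) and Irs3, an insulin receptor substrate, 15.4-fold lower (10.4 to 23.7). Lpl, lipoprotein lipase, was 33.9-fold lower (16.1 to 85.6), Aox4, an aldehyde oxidase, 31.7-fold lower (13.2 to 99.3), at 8.57 and 50.1 CPM in letters A and B, and Trdn, triadin, 23.5-fold lower (10.4 to 65.4). Tcap and Zfp804b had 2 UMIs each in GAP cells and were 116.01-fold (31.6 to 966) and 46.3-fold (12.3 to 390) lower. That these genes stayed lower in GAP with any letter left out follows from the condition on the 4 pairings by which they were chosen. Some sizes moved. The smallest were 9.20-fold for Aox4, 21.2-fold for Ppp1r1b, 19.1-fold for Entpd8 and 22.4-fold for Lpl without letter B. For Tcap and Zfp804b the smallest were 52.7-fold and 21-fold, without letter C. Slc5a11 was 47.9-fold and Irs3 27-fold lower without letter C, and Ltbp2 37.1-fold lower without letter D.

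Across the matrix, 10152 genes reached 10 CPM in a genotype, and 5743 of them met the conditions on cells and letters. Of these, 1216 were at least 2-fold higher in GAP and 596 at least 2-fold higher in control cells, with a median log2 ratio over all 10152 genes of 0.10. These counts describe size and not a test, and they depended on the handling of low genes: a pseudocount of 10 CPM gave 775 and 371, and a filter of 50 CPM gave 475 and 337, and no filter gave 1874 higher in GAP.

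The gene lists show which programs these differences touch. All 3 general hair cell lists were far higher in GAP cells. Of the 14 measured genes of the fate list, 10 were at least 2-fold higher and 0 lower, with a median log2 ratio of 3.87 (3.98 with genes at 0 in control set to their bound), and the 11 members other than the transgene genes had a median of 3.63. Of 30 hair bundle and mechanotransduction genes, 24 were at least 2-fold higher (median 3.91, 4.10 with bounds). Of 18 synapse, calcium buffer and channel genes, a list that also holds Gfi1, 15 were at least 2-fold higher and 1 lower (median 3.82, 4.10 with bounds). Each median lay above those of all 10000 matched random lists, and over the 4 letter pairings the medians ranged from 3.63 to 4.77, from 3.11 to 4.13 and from 3.05 to 4.04. The log2 ratios of the lists' summed CPM were 1.61, 1.93 and 4.18.

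Bundle genes were led by Myo6, an unconventional myosin of the hair cell apex, at 1115 against 171.2 CPM (6.51-fold, 6.02 to 7.06). Cib2, a component of the transduction complex, was at 261 against 14 CPM (18.6-fold, 14.3 to 24.8), Myo7a at 216 against 23.5 CPM (9.19-fold, 7.44 to 11.5) and Triobp, which bundles actin in the rootlets of stereocilia, at 672 against 195 CPM (3.45-fold, 3.19 to 3.73). Lmo7, Pcdh15 and Ush1c were already at 251, 226 and 133.5 CPM in control cells and were 1.21-fold, 1.26-fold and 1.22-fold higher. Among the synapse genes, Otof, the calcium sensor of the ribbon synapse, was at 122.8 CPM against 0 UMIs (at least 163.8-fold), Pvalb, a calcium buffer, at 81.6 CPM against 0 UMIs (at least 108.9-fold) and Pcp4 at 243 against 13.5 CPM (18-fold, 13.7 to 24.1). Otof was at 167.2 CPM in letter C and 69.4 CPM in D and Pvalb at 107.5 and 50.5 CPM, and the 5 cells with most UMIs held 66.4% of the Otof and 75.6% of the Pvalb UMIs of the authors' cluster 2. Anxa4 was 8.85-fold higher (7.23 to 10.9), whereas Cacna1d, the calcium channel of the ribbon synapse, was at 55.3 and 69.5 CPM, 1.26-fold lower (1.06 to 1.48). In the fate list Jag2 was 13.8-fold higher (10.4 to 18.6), and Eya1 and Tbx2, which control cells also expressed, had ratios of 1.32 and 0.740.

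Genes of inner and of outer hair cells were listed separately, and the difference between the lists was not tested. The inner hair cell list had a median log2 ratio of 3.81 (4.12 with bounds, above all 10000 random lists), and 6 of its 7 measured genes were at least 2-fold higher, the seventh being Tbx2 at a ratio of 0.740. Its log2 ratio of summed CPM was 1.07 and its median without a filter on level 2.53. Cabp2 was at 76.4 CPM with 1 UMI in control cells (306-fold, 54.6 to 12104, and 151.6-fold without letter B), Brip1 5.66-fold higher (4.73 to 6.81), Shtn1 2.68-fold higher (2.32 to 3.09), Calb2 at least 23.1-fold higher and Slc17a8, the vesicular glutamate transporter of inner hair cells, at 13 CPM, at least 17.4-fold higher, with 18.8 CPM in letter C and 6.16 CPM in D. The outer hair cell list had a median of 1.11 at the 96.6th percentile, with 3 of 6 measured genes at least 2-fold higher, a log2 ratio of summed CPM of 0.46 and a median of 0.31 without letter D. Bcl11b was 11.8-fold higher (4.84 to 37.3, and 5.84-fold without letter B) and Chrna10 at 13.2 CPM, at least 17.6-fold higher, while Ikzf2 was 1.98-fold lower (1.54 to 2.56). Lbh was 1.64-fold lower (1.34 to 2.02), but letter A held it at 81.1 CPM against 25.8, 22.2 and 44.7 CPM in B, C and D, and the ratio was 1.26 without letter A. Ocm, oncomodulin, and Slc26a5, prestin, were looked up after the other values were seen: Ocm had 0 UMIs in either genotype, which allows up to 0.559 CPM in GAP cells, and Slc26a5 had 4 UMIs in GAP and 0 in control cells.

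Lists of supporting and other non-sensory cells had medians on both sides of 0, with members on both sides. The general supporting cell list had a median log2 ratio of -0.28 over 17 genes (4.79th percentile), but 0.090 without letter A, 0.090 as a log2 ratio of summed CPM and 0.031 without a filter on level. S100a1 was 1.55-fold higher in GAP cells (1.53 to 1.58), and Sox10, Gjb2 and Cldn9 were 1.99-fold, 1.79-fold and 1.31-fold lower. The pillar and Deiters cell list had a median of 0.75 (99.6th percentile) but a log2 ratio of summed CPM of -0.30, with Cntn1 1.81-fold lower (1.68 to 1.94). Lgr5, a receptor of the Wnt pathway, was 1.69-fold higher in GAP as a pool (1.57 to 1.82), but the letters of a genotype differed more. It was at 417 and 100.6 CPM in A and B and at 297 and 601 CPM in C and D. Its ratio was 1.04 without letter B and 4.32 without letter A. The inner sulcus and tectorial membrane list had a median of 0.01 (44.4th percentile), with Epyc 1.89-fold and Otoa 1.5-fold lower. The lists of Hensen, Claudius and outer sulcus cells and of the stria vascularis had medians of -0.25 and -0.64 (percentiles 8.16 and 0.23), the first turning to 0.045 as a mean of per-cell CPM and 0.12 after thinning, with Slc26a4, pendrin, 2.94-fold lower (2.78 to 3.13) and Kcnj10, a potassium channel, 3.06-fold lower (2.88 to 3.25).

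The Notch list was higher in GAP cells, with a median log2 ratio of 2.26, above all 10000 random lists, and 9 of 13 measured genes at least 2-fold higher. The median was 1.62 as a mean of per-cell CPM, 1.26 after thinning and 1.38 as a log2 ratio of summed CPM, and 2.85 without letter A and 1.64 without letter C. Heyl, a Notch target, was at 490 against 64.5 CPM (7.60-fold, 6.68 to 8.67), and Notch1 was 1.74-fold higher. Jag1 was 2.27-fold higher (2.02 to 2.56), at 142.6 and 45.1 CPM in letters A and B and 216 and 209 CPM in C and D, and 1.49-fold without letter B and 4.71-fold without letter A. Notch2 was 1.2-fold higher but had a ratio of 0.889 without letter C. The list of p53 and apoptosis genes had a median of 0.62 (95th percentile), with Cdkn1a 2.03-fold (1.82 to 2.27) and Ccng1 2.25-fold higher (1.90 to 2.69) and Trp53inp1 1.47-fold lower. The immediate early and dissociation stress list had a median of -0.24 (percentile 10.2), with Fosb 1.63-fold and Jun 1.06-fold lower (Jun 1.14-fold higher without letter D), and the mitochondrially encoded genes, a guide to RNA quality, a median of 0.02 (56.9th percentile).

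Many markers of other cells in the sort were at low levels, though not those of Schwann and satellite glia, and some of the ratios rested on few cells. The erythroid list had a median log2 ratio of 4.01 (4.33 with bounds), but 284 of the 360 Hbb-bs UMIs in GAP cells were in 1 cell of letter C, and letter D held Hbb-bs at 0.410 CPM. The cell cycle list had a median of 1.58 with a range of 0.47 to 3.62 over the pairings, 0.63 after thinning and 0.99 without letter A, and 1 cell of letter C likewise held most Mki67 UMIs of the GAP cells, while Ccnd1 was at 204 CPM in C and 58.7 CPM in D against 3.02 and 4.46 CPM in A and B. The Reissner membrane list had a median of 2.38 with a range of 0.59 to 3.22 over the pairings. The list of other Atoh1 lineages had a median of 1.35 (99.8th percentile, range 0.50 to 2.38). Its member Scg2 was 4.19-fold higher in GAP, but 1 cell of letter D held most of its UMIs, and the ratio was 0.895 without letter D. Krt8 and Krt18 of this list, 1.62-fold and 1.73-fold higher, stayed higher with any letter left out. Endothelial and pericyte genes had a median of 1.23 over 3 genes (range over the pairings -1.07 to 5.26), with Rgs5 at 97.6 against 1 CPM (4 UMIs). The fibroblast list had a median of 1.68 over 4 genes but a log2 ratio of summed CPM of -1.09, since Lum, its most abundant member, was 3.25-fold lower (2.94 to 3.61, and 5.31-fold without letter D). Schwann and satellite glia genes had a median of -0.63 (percentile 1.41). Their summed level was 1189 CPM in GAP and 2150 CPM in control cells. Sox10, the member with most UMIs, is also in the general supporting cell list, so this median is no measure of glial cells alone. The leukocyte list had 1 measured member, Cd74, at 3.54 against 13 CPM, a log2 ratio of -1.62 that rested on letter A, which held Cd74 at 25.7 CPM against 0.50, 1.71 and 5.75 CPM in B, C and D. Without letter A Cd74 was 7.14-fold higher in GAP, and the list was at 0.45 without letter C and 0.71 as a log2 ratio of summed CPM. No neuron gene reached 10 CPM, and Nefh, the member with most UMIs, had 43 UMIs in GAP and 0 in control cells.

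**Figure D2:**
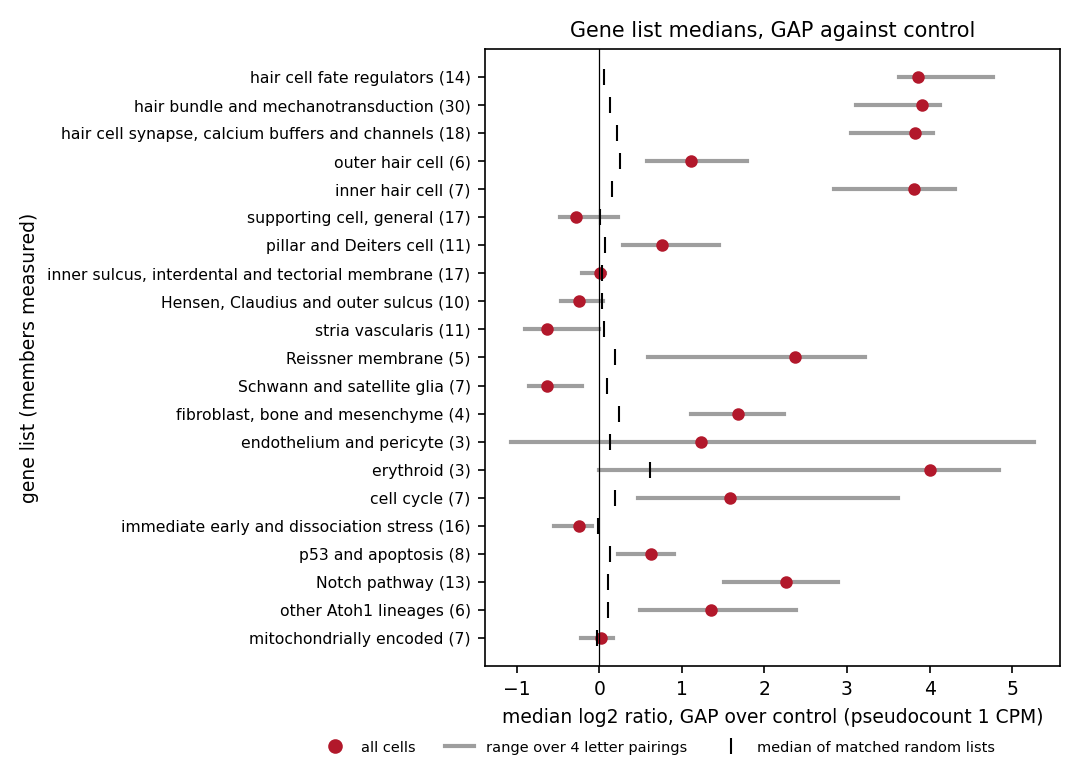
Median log2 ratio of GAP over control (horizontal axis) for gene lists with at least 3 measured members, with the number measured in parentheses; points are all cells, grey bars the range over 4 pairings of letters and ticks the median of 10000 matched random lists. The fate, bundle and synapse lists lie at 3.87, 3.91 and 3.82, and the general supporting cell list at -0.28.

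The third comparison concerned the authors' clusters. Control cells were annotated mainly to clusters 0, 3, 4 and 6, named WT Cells 1, WT Cells 2, WT Supp Cells and WT Cells 3, which held 80, 29, 29 and 20 control cells. The 2 control letters differed in this mixture. Of their cells with a cluster, 31.1% of A and 59.1% of B were in cluster 0. For clusters 3, 4 and 6 the shares were 20%, 22.2% and 13.3% in A and 12.5%, 10.2% and 9.09% in B. GAP cells were annotated mainly to cluster 1 (Reprogammed Sup Cells 1, 54 cells), cluster 2 (Reprogrammed Hair Cells, 51 cells) and cluster 7 (Reprogrammed Supp Cells 2, 20 cells). Together these 3 clusters held 76.7% of the GAP cells with a cluster (69.4 to 82.9), with 73.1% in letter C and 80% in letter D, and 0 control cells, which allows up to 1.69%. The cluster of reprogrammed hair cells alone held 31.3% of GAP cells (24.3 to 39). Clusters 5 and 8, which the authors named Reprogrammed Unknown 1 and Reprogrammed Unknown 2, held 13 and 10 GAP cells and 13 and 7 control cells. Cluster sizes follow the genes that separate the genotypes, and the sort and the plates can set them, so these shares describe the annotation. A separate clustering of the counts put 73.9% of GAP cells in clusters with over 90% GAP cells, and 63.3% in clusters with no control cell.

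The fourth comparison followed hair cell genes across these clusters. Levels between clusters describe their identity, since such genes can enter the clustering. Cluster 2 held Myo7a at 452 CPM (95% interval 418 to 488), against 128.5 CPM in cluster 1 and 35.1 CPM in cluster 7, and in control cells Myo7a ranged up to 101.7 CPM, in cluster 5. Several genes of mature hair cells, picked after their values were seen, were higher in cluster 2. Slc17a8 was at 29.8 CPM there and 0.563 CPM (1 UMI) in cluster 1, Lhfpl5, a subunit of the transduction channel complex, at 92.8 and 4.51 CPM, Strc, stereocilin, at 33.9 and 2.25 CPM, and Tmc1, a pore-forming transduction channel protein, at 89.3 and 21.4 CPM. Ccer2 went the other way, at 4659 CPM in cluster 1, 1048 CPM in cluster 2 and 439 CPM in cluster 7. Atoh1 was at 1097, 815 and 503 CPM in clusters 1, 2 and 7.

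Within cluster 2 these genes came from few cells. The 5 cells with most UMIs held 97.8% of the Lhfpl5 UMIs, 79.1% of the 43 Slc17a8 UMIs and 73.6% of the Tmc1 UMIs, compared with 36% of the 653 Myo7a UMIs. After thinning to 8000 UMIs, a cell of cluster 2 had a median of 18 of the 73 hair cell genes (quartiles 15 and 25.5, range 9 to 52) and a cell of cluster 1 a median of 19 (range 11 to 29). Cluster 7 had a median of 15.5, GAP cells of the shared clusters 10.5 and control cells 7, with a highest control cell at 13 genes. Without thinning the medians were 26 in cluster 2, 27 in cluster 1, 18 in cluster 7, 16 in GAP cells of the shared clusters and 10 in control cells. Of all 180 GAP cells, 71.7% had more hair cell genes than any control cell (64.5 to 78.1), with 77.2% in letter C and 65.9% in letter D. In the 38 GAP cells of the shared clusters this share was 18.4% (7.74 to 34.3). Carry-over of RNA between wells, weighed in the closing section, is not excluded here. It could lift GAP cells over a limit that was set by cells of the control plates. The count is a range and not a class of cells, with 9 GAP cells at 13 genes and 16 at 14. At least 30 hair cell genes were detected in 15 GAP cells, 11 of them in cluster 2 and 4 without a cluster.

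**Figure D3:**
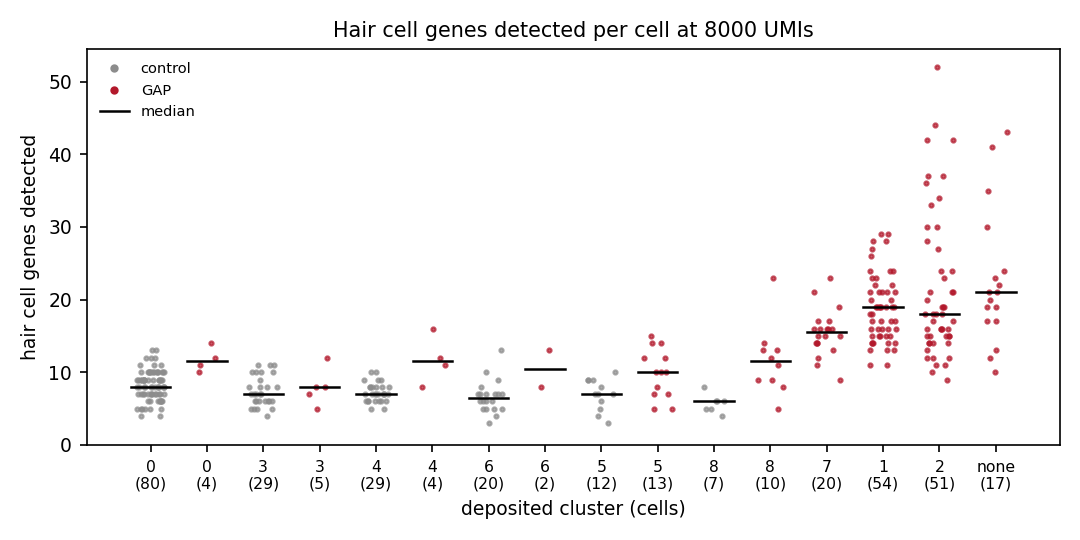
Number of hair cell genes detected per cell (vertical axis, of 73 with a UMI, the transgene genes left out) after thinning to 8000 UMIs, by deposited cluster and genotype, with the number of cells in parentheses; each point is a cell and bars are medians. Cluster 2 reaches from 9 to 52 genes, cluster 1 from 11 to 29, and no control cell is above 13.

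The fifth comparison looked within a cluster, and only cluster 5 had at least 10 cells of each genotype, 13 and 13. The GAP and control cells in it differed broadly. In GAP cells Serping1, the C1 inhibitor, was at 379 CPM, Cyp2b10, a cytochrome P450, at 333 CPM, Lcn2, lipocalin 2, at 322 CPM and Fmo2, a flavin monooxygenase, at 288 CPM, all with 0 UMIs in the control cells and so at least 42.2-fold, 37.1-fold, 35.8-fold and 32-fold higher. Ccer2 and Tmem255b followed at 251 and 170.8 CPM against 0 UMIs, beside 270 and 192 CPM in the GAP cells of cluster 8. In the GAP cells of clusters 0, 3, 4 and 6 Ccer2 was at 243, 268, 229 and 197 CPM. Its level was thus not particular to cluster 5. Carry-over of RNA between wells, weighed in the closing section for other genes, was not tested for Ccer2. Control cells held Serpine2, a protease inhibitor, at 224 CPM (at least 26.3-fold higher than in GAP), Ltbp2 at 189 CPM, Dhrs7 at 101.7 CPM, Tmem79 at 98.7 CPM and Syt11 at 65.8 CPM, all with 0 UMIs in GAP cells, and Ank2, ankyrin B, at 527 CPM against 2 UMIs, 92.5-fold higher (25.2 to 770).

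By list, 12 of 16 general supporting cell genes were at least 2-fold lower in the GAP cells of cluster 5 (median log2 ratio -2.34), as were 10 of 17 inner sulcus and tectorial membrane genes (median -1.97). Hair cell lists other than that of inner hair cells had members on both sides. Of 20 hair bundle genes 12 were at least 2-fold higher and 4 lower (median 1.36), and of 7 synapse genes 4 and 2 (median 1.63). Of 10 fate genes, transgene genes included, 5 were higher and 1 lower (median 0.98), and of 5 outer hair cell genes 1 and 3 (median -1.49). Of 4 inner hair cell genes 2 were higher and 0 lower (median 1.02). Carry-over of RNA between wells, weighed in the closing section, is not excluded for hair cell genes in these GAP cells. Among markers of other cells, 2 of 3 Reissner membrane genes (median 2.98), 2 of 3 endothelial and pericyte genes (5.01), 2 of 2 leukocyte genes (2.72), the 1 measured erythroid gene (5.25) and 3 of 4 genes of other Atoh1 lineages (2.11) were at least 2-fold higher, while of 4 fibroblast genes 1 was higher and 2 were lower (-1.11). Of 16 immediate early and dissociation stress genes 5 were higher and 0 lower (0.65), and of 11 p53 and apoptosis genes 5 and 2 (0.68). Of 7 mitochondrially encoded genes 0 were higher and 0 lower (0.0012). Of 5 cell cycle genes 4 were higher (3.63), but 1 cell of letter C held 97.6% of the Mki67 UMIs of these GAP cells, and without it the list had 2 of 4 genes higher and a median of 2.24. With any 1 of the 26 cells left out, a comparison chosen after the values were seen, the medians ranged from 0.92 to 1.73 for bundle, 1.04 to 3.63 for synapse, 2.503 to 5.18 for endothelial and pericyte, 1.58 to 4.32 for leukocyte and -2.48 to -0.014 for fibroblast genes. They ranged from -3.10 to -2.22 for general supporting cell, -2.46 to -1.05 for inner sulcus and tectorial membrane and 2.35 to 4.14 for Reissner membrane genes. The ranges were 0.58 to 1.62 for fate, 0.34 to 1.53 for inner hair cell and 0.060 to 0.87 for stress genes. Members at least 2-fold higher fell to as few as 8 for bundle genes and 1 for leukocyte genes. Of 4307 genes that met the conditions, 821 (19.1%) were at least 2-fold higher in GAP and 894 (20.8%) at least 2-fold higher in control cells. Of the 13 GAP cells 11 were from letter C. Without letter A, B or C fewer than 10 cells of a genotype remain (7 control, 6 control and 2 GAP cells), so whether these shares rest on 1 letter was not tested for them.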

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

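The tests of carry-over, weak activity, few cells, wrong labels and the gene-number limit were chosen after the results were seen, and for the correlations of cluster 5 and for wells with 2 cells a criterion written earlier was met before a further comparison was added. The test of wrong labels was also divided by kind of cell, and given a condition on carry-over, after its first outcome was known.

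The 17 GAP cells to which the authors gave no cluster enter no comparison of clusters, and they held the transgene genes above the level in control cells. Atoh1 was at 1109 CPM in them (95% interval 1040 to 1182), Gfi1 at 296 CPM (260 to 334) and Pou4f3 at 928 CPM (865 to 995). The 2 control cells without a cluster had 0 UMIs of these genes, in 14914 UMIs in total.

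Why these cells have no cluster was weighed against 2 explanations. The range of genes per cell separates them fully: cells with a cluster had 2079 to 6044 genes, the 17 GAP cells 6065 or more and the 2 control cells 1981 or fewer, with 0 cells without a cluster inside the range, as a filter on the number of genes detected could give. Wells with 2 cells are a candidate cause of such high numbers: at 8000 UMIs the 17 cells had a median of 3332 genes (quartiles 3311 and 3451), nearer to 3391 in 200 simulated pairs than to 3096 in single cells of clusters 1 and 2, which met the criterion set beforehand. The 17 clustered GAP cells with most genes, a comparison added afterwards because the unclustered cells stand out by gene number, had a median of 3292, nearer to 3332 than the pairs, and with it wells with 2 cells cannot be told apart from single cells rich in RNA. The rule for this added comparison was itself changed once after its outcome was known.

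GAP cells in the clusters shared with control cells held genes of clusters 1, 2 and 7 at a low level. This was measured over 18 genes chosen by level, some of them outside the hair cell lists, such as Nos1, Grp and Tnc. They were under 0.5 CPM in control cells and at 100 CPM or more in clusters 1, 2 and 7. The 38 cells held 427 UMIs of them, a median of 8.72% of the level in clusters 1, 2 and 7. A few misplaced cells are argued against, since the 3 cells with most of these UMIs held 23.4% of them, and every cell held 3 to 41. Carry-over of RNA between wells may account for it, since the fraction was alike across genes (upper over lower quartile 1.48), and of 11 genes with at least 100 UMIs and most of all their UMIs in 1 cell, 9 had more UMIs in other cells of that letter than in the other letter of the genotype and 2 fewer; of Muc5b, 1 cell of letter C held 432 UMIs, and 46 of 91 other cells of C but 2 of 88 of D had a UMI. Weak activity of the GAP allele stays open, since the transgene genes lay at 0.968 times the fraction of the other genes, between the bounds that would decide.

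Cluster 5 holds 13 control and 13 GAP cells that differ broadly. Wrong labels are argued against for cells like those of clusters 1, 2 and 7, since 0 of the 13 control cells reached the 4 UMIs of Atoh1, Gfi1, Pou4f3 and Ccer2 that the lowest of those cells held, and for cells like the GAP cells of cluster 5, since 11 control cells lay above the upper quartile of the GAP cells in the summed level of general supporting cell genes (medians 14196 and 1930 CPM) and 2 did not. Wrongly labelled cells like the GAP cells of the other shared clusters stay open, since those held supporting cell genes at a median of 10339 CPM and their transgene UMIs may be carry-over, which a GAP cell on a control plate would lack. A residual cluster that joins unlike cells may account for it: across 10152 genes, which are not independent replicates, the control cells had a Spearman correlation of 0.710 with the GAP cells of cluster 5 and 0.787 with the control cells of cluster 0, a difference of 0.0771 that met the criterion of 0.02 set beforehand. With cluster 0 drawn down to 13 cells, a comparison added afterwards, the difference was 0.0158 and the lowest of 100 draws 0.705. The draws matched numbers of cells and not UMIs, with medians of 19822 per control cell of cluster 0 and 28085 per GAP cell of cluster 5. In the separate clustering, the cluster where deposited cluster 5 was most common held 13 GAP and 2 control cells. At most 2 of the 13 control cells were thus in it, which goes with a residual cluster. How the other cells of cluster 5 were placed was not examined, so this explanation stays undecided.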

How the results depend on the processing

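Values without a test are given here, and the settings that limit cells or genes to those with a cluster, to 15000 UMIs, without abundant RNAs, without clusters 5 and 8, without the transgene genes, to all cells as denominator, to own clusters with no control cell and to cluster 5 without a single cell were chosen after seeing the data. No paired analysis was possible because replicate numbers follow accession order only and no test was made. Of 471 alternative values, 273 stayed within the counting interval or 1.5 times a count, 187 moved and 11 turned direction. The cause was not tested unless stated. This tally does not measure robustness, since some of the values could not move. A minimum of 5000 UMIs removed no cell, and leaving out a control letter leaves levels in GAP cells as they are. Most lists hold no transgene gene to remove. The counting intervals of the inner hair cell and erythroid lists have no width, so any difference counts as moved there. With the mean of per-cell CPM, GAP cells held Atoh1 at 727, Gfi1 at 182 and Pou4f3 at 487 CPM, and the fate, bundle and synapse medians were 4.31, 3.69 and 3.58. TMM gave 3.79 for the synapse and -0.35 for the general supporting cell list, and median of ratios 3.78 and -0.36. Thinning gave Atoh1 at 712.5 CPM, Pou4f3 at 463 CPM and a bundle median of 3.598. A pseudocount of 10 CPM gave 775 and 371 genes at least 2-fold higher in GAP and in control, and fate, bundle and synapse medians of 2.38, 2.02 and 1.53, which a larger pseudocount lowers by construction. A filter of 50 CPM, which leaves fewer genes, gave 475 and 337 genes and medians of 6.14, 3.15 and 5.01. No filter gave 1874 genes higher in GAP, medians of 2.95, 3.56 and 3.11, and 0.031 for the supporting cell list. The log2 ratio of summed CPM gave 1.61, 1.93 and 4.18, and 0.090 for the supporting cell list. The synapse median was 3.597 in cells with a cluster, 3.90 without abundant RNAs and 3.96 without clusters 5 and 8. Own clusters with no control cell held 63.3% of GAP cells, against 73.9% in own clusters with over 90% GAP cells, since an own cluster with 19 GAP and 2 control cells passes only the second limit.

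Leaving out each letter gave ranges of 805 to 806 CPM for Atoh1, 182 to 221 for Gfi1 and 522 to 634 for Pou4f3, and medians of 3.58 to 4.54 for fate, 3.49 to 4.20 for bundle, 3.58 to 3.83 for synapse and -0.57 to 0.090 for the supporting cell list, the last without letter A. Genes higher in GAP ranged from 1116 to 1552 and in control from 689 to 792, against 1216 and 596 with all letters. With a letter left out fewer pairings have to keep the direction, which loosens the condition by construction. In the deposited clusters, the share in clusters with over 90% GAP cells ranged from 73.1% to 82.8%, against 76.7% with all letters. Its upper end came without letter A, which holds 6 of the 7 control cells of cluster 8, so that this cluster passes the limit. Within cluster 5 leaving out letter A, B or C is not reported, since fewer than 10 cells of a genotype remain, the minimum set for this comparison, which was applied here after these values were seen. Without letter D the shares were 16.4% and 23.2%. Of the other lists, 8 alternative medians turned: Hensen, Claudius and outer sulcus to 0.045 (per-cell mean) and 0.12 (thinned), leukocyte to 0.45 (without letter C, and -2.56 without letter B), 0.95 (no filter) and 0.71 (summed CPM), fibroblast to -1.69 (filter of 50 CPM) and -1.09 (summed CPM), and pillar and Deiters to -0.30 (summed CPM). Depth limits genes near 0 in control cells, where 3 counts are 0.750 CPM.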

Other observations

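Both the genes named here and the test of the nearest control cluster were chosen after the results were seen. Several genes outside the hair cell lists were nearly absent from control cells and high in clusters 1, 2 and 7 together. Slc8a2, a sodium-calcium exchanger, was at 132.3 CPM and Atp2b3, a plasma membrane calcium pump, at 148.5 CPM in these clusters, both with 0 CPM in control cells. Grp, gastrin-releasing peptide, was at 100.5 CPM and Nos1, neuronal nitric oxide synthase, at 140 CPM, also against 0 CPM. Dlk2, a Delta-like protein, was at 163.4 CPM, Tnc, the matrix protein tenascin C, at 128.05 CPM and Lmo1, a LIM-domain cofactor, at 111.8 CPM, against 0.5, 0.25 and 0.5 CPM. In GAP cells of the shared clusters Nos1 was at 47.9 CPM and the other 6 genes between 6.39 and 20.2 CPM.

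A hypothesis is that the cells of cluster 2, named reprogrammed hair cells by the authors, may derive from cells like the control cells of cluster 3. Over 1457 genes that separate control clusters 0, 3, 4 and 6 and are in no hair cell list, cluster 2 had its highest Spearman correlation with the control cells of cluster 3, 0.594, against 0.410, 0.281 and 0.327 with clusters 0, 4 and 6, a difference of 0.184 from the next. Cluster 1 had its highest with control cluster 0, 0.568, and cluster 7 with control cluster 4, 0.670. With each gene centred on its mean over clusters 1, 2 and 7 and over the 4 control clusters in turn, cluster 2 was at 0.478 with control cluster 3 and 0.105 with the next, and cluster 7 at 0.583 with control cluster 4, whereas cluster 1 was nearly as close to control cluster 6 (0.312) as to control cluster 0 (0.335). Likeness across genes, which are not independent replicates, does not show descent, and the authors' clustering can have used the same genes.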
